A study of Mus musculus with 17 samples.

How the data were processed

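RNA of 17 mammary tumours was measured, 1 array per tumour, with biotin-labelled cRNA from total RNA prepared by the standard Affymetrix protocol, per the labels' protocols. The deposited values are log2 values per probe set, for 22690 probe sets with none missing. The sources do not state how the authors normalised them, and the log2 scale was read from the values themselves. Array medians lay between 7.23 and 7.40, so the deposited values were used without further normalization, by a rule fixed before the data were examined. The 3 arrays with TM titles had minima of 2.47 to 2.63 against 3.07 to 3.23 on the 14 others. On all 3 TM arrays 2989 probe sets had one exactly equal value, and on any 3 numbered arrays at most 1 probe set did.

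Of the probe sets, 64 were Affymetrix controls and were left out of the gene tests, 20380 were paired with one gene symbol by the supplied probe table, 691 with several and 1555 with none. The supplied gene table matched 20351 of them by gene identifier. For each of 12393 genes the probe set with the highest mean over all arrays was used, and 4956 genes had several. The 31 gene lists were written from general knowledge before the data were examined, with 627 entries, of which 558 were measured, and each list had 7 to 32 measured genes. Of the genes 7 were in more than 1 list. Several adipocyte and milk genes, among them Lpl and Cidea, are also expressed by secretory mammary epithelium.

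Samples were grouped by the histology label. EMT (n = 6) and Squamous (n = 9) tumours were compared with limma 3.58.1 in R 4.3.3, with histology and title format as additive terms, moderated tests and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05 on the adjusted p. The Papillary and Microacinar tumours stayed out of this fit. The labels do not say whether tumours came from separate animals. The title number 1407 occurs on Squamous 7 and Squamous 8 and the title number 1308 on Squamous 5 and the Microacinar tumour. The p-values therefore measure only the spread between these tumours, part of which may be technical. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, with fry, and with an exact permutation test of the list means that was added after the data were seen. Counts adjusted over the list alone use the same limma p-values.

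Principal components were computed from centred, unscaled genes of all tumours with numpy 2.4.6, and each sign was set so that EMT tumours score higher. RNA integrity was read from the 3′ minus 5′ log2 difference of the Gapdh and beta-actin control probe sets. A higher difference means less intact RNA. Group differences in component scores and in RNA integrity were tested by exact two-sided permutation over 5005 splits, or 495 among numbered arrays. Single tumours were set against 10000 random lists of equal size, drawn from 20 bins of mean expression, and lists under the percentile of 2.5 or above 97.5 were counted. Correlations used exact permutation of pairings. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

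The named genes followed a rule fixed before the data were examined. It took the 10 highest and 10 lowest genes past the threshold and up to 3 such members per list, which gave none, then Myc, Cdh1, Epcam, Vim, Zeb1, Krt5, Krt14 and Krt8, the member of a list with the largest absolute fold change, and for each single tumour the 6 genes furthest above and the 4 furthest below all others, among genes above the median level. Genes outside it were chosen after their values were seen: Wap, Btn1a1, Cldn8, Xbp1, Lpl, Cidea in the EMT comparison, Aurka, Dusp6, Spred1, Spred2, Ms4a1, Cdk4, Smtn, Lmod1 and the pair of Krt8 with Krt18.

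The model was tested on simulated data with the spread of the EMT and Squamous fit over 12393 genes. It recovered 37 of 50 genes changed by a log2 fold of 1 and 50 of 50 at each of 2, 3 and 4, with 20 false calls, and camera recovered 5 of 5 shifted lists and called 0 of 15 others. The simulated genes varied independently of one another. A changed gene shifted by the same amount in every EMT tumour, with equal spread in both groups. In the real data Muc15, with a large fold, had an SD of 3.38 in EMT and 1.02 in Squamous tumours. The recovery therefore does not show that such uneven changes would be called. Real lists also had estimated correlations such as 0.909 for skeletal muscle and 0.760 for epithelial junction, so the list recovery does not carry over to them. The alternatives tried were no title format term, each title format alone (the TM format, with 1 Squamous tumour, without a call), quantile normalization, subtracted array medians, the mean of probe sets, all probe sets, genes above the median level, a trended and robust fit, array weights, all 17 tumours in 4 groups, the 1407 tumours averaged, leaving out each tumour, a fold threshold, leaving out genes in more than 1 list, other list tests and, added after the data were seen, leaving out genes equal on the TM arrays.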

Results

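RNA from 17 mammary tumours of FVB mice was measured on Affymetrix mouse arrays, 1 array per tumour. The series describes the tumours as induced by Myc T58A, a mutant form of the Myc transcription factor, under the MMTV promoter, which is active in mammary epithelium, and as low expressing. The histology label divided them into 9 Squamous tumours, 6 EMT (epithelial to mesenchymal transition) tumours, 1 Papillary tumour and 1 Microacinar tumour. Replicate numbers only tell tumours of one label apart. All values are log2 values per gene, as deposited; the number of tumours limits their precision. The array titles had 2 formats: 14 arrays had numbered titles, and 3 (EMT 5, EMT 6 and Squamous 9) had titles in which TM follows a number. The title format was a term of the gene model, because the 2 formats may mark 2 sets of arrays and both hold both histologies. The TM arrays also had a wider distribution of values, with an SD over probe sets of 2.46 to 2.51 against 2.25 to 2.29 on the numbered arrays. The TM arrays hold 2 EMT tumours and 1 Squamous tumour, too few for a call within them. Without Squamous 9 the title format term also takes up EMT 5 and EMT 6, and the fold changes equal those among numbered arrays. Fold changes below come from that model, EMT minus Squamous, while means are those of the values themselves.

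Myc itself averaged 11.09 ± 1.01 (SD, n = 9) in Squamous tumours and 10.37 ± 1.15 (SD, n = 6) in EMT tumours, a log2 fold change of −0.51 (SE 0.53, adjusted p = 0.685 with limma). The Papillary tumour had a value of 10.20 and the Microacinar tumour 10.28. Among EMT tumours Myc ranged from 9.18 in EMT 4 to 12.40 in EMT 1. The sources do not say whether its probe set reads the transgene as well as the mouse gene.

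The comparison of EMT with Squamous tumours asks how expression differs between the 2 histologies that have replicates. Cdh1 (E-cadherin, the adhesion protein of epithelial junctions) lay between 11.13 and 11.97 in the 9 Squamous tumours, and at 7.19 in EMT 4, 8.10 in EMT 5 and 7.04 in EMT 6. EMT 1, EMT 2 and EMT 3 had Cdh1 values of 11.91, 12.09 and 11.84. Epcam, an epithelial surface protein, followed the same tumours, with 7.09, 5.92 and 7.56 in EMT 4, EMT 5 and EMT 6 and 12.18, 11.64 and 12.62 in EMT 1, EMT 2 and EMT 3. Zeb1, a repressor of Cdh1, was 10.13, 9.78 and 10.48 in EMT 4, EMT 5 and EMT 6, above the highest Squamous value of 8.97. Vim, the mesenchymal intermediate filament protein, was 12.41 ± 0.89 (SD, n = 9) in Squamous and 13.00 ± 0.67 (SD, n = 6) in EMT tumours. The log2 fold changes were −1.42 for Cdh1 (SE 0.69), −1.61 for Epcam (SE 0.79), 0.58 for Zeb1 (SE 0.37) and 0.42 for Vim (SE 0.40), with limma adjusted p of 0.368, 0.369, 0.496 and 0.659.

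The mean of the 30 epithelial junction genes was 9.64 ± 0.22 (SD, n = 9) in Squamous and 7.95 ± 2.05 (SD, n = 6) in EMT tumours. It was 6.41 in EMT 4, 5.79 in EMT 5 and 6.07 in EMT 6, below the lowest Squamous tumour at 9.14, and 9.77, 9.67 and 9.99 in EMT 1, EMT 2 and EMT 3. The median log2 fold change of the list was −1.44, with −0.80 without EMT 4 and −0.73 with array weights. Among numbered arrays it was also −0.73 (the estimate left without Squamous 9, when EMT 5 and EMT 6 drop out too). In this list 0 members passed the test over all genes or adjusted over the list alone. Esrp1, an epithelial splicing regulator, had the largest fold change of the list at −2.50 (SE 0.97, adjusted p = 0.281). The 23 mesenchymal transition genes lay higher in EMT tumours, with a median log2 fold change of 0.58 that was 0.25 without EMT 4 (camera adjusted p = 0.0491), and 0 members passed over all genes or adjusted over the list alone. Twist1, a transcription factor of mesenchymal cells, had the largest change at 1.44 (SE 0.45, adjusted p = 0.215). By camera with a preset correlation the adjusted p was 1.53e-10 for epithelial junction and 0.000645 for mesenchymal transition, and with an estimated correlation the adjusted p was 0.499 and 0.680. The mesenchymal transition call ended with array weights (median 0.12, camera adjusted p = 0.465). The lowest array weights were 0.40 for EMT 4 and 0.42 for EMT 2, so this setting partly repeats leaving out these tumours. Fibroblast matrix genes moved with this list across tumours: relative to the Squamous mean, the mesenchymal transition and fibroblast matrix means were 1.58 and 2.00 in EMT 4, 1.07 and 1.42 in EMT 5, 1.39 and 0.65 in EMT 6, −1.45 and −2.02 in Squamous 1 and −1.24 and −1.58 in Squamous 2.

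**Figure D1:**
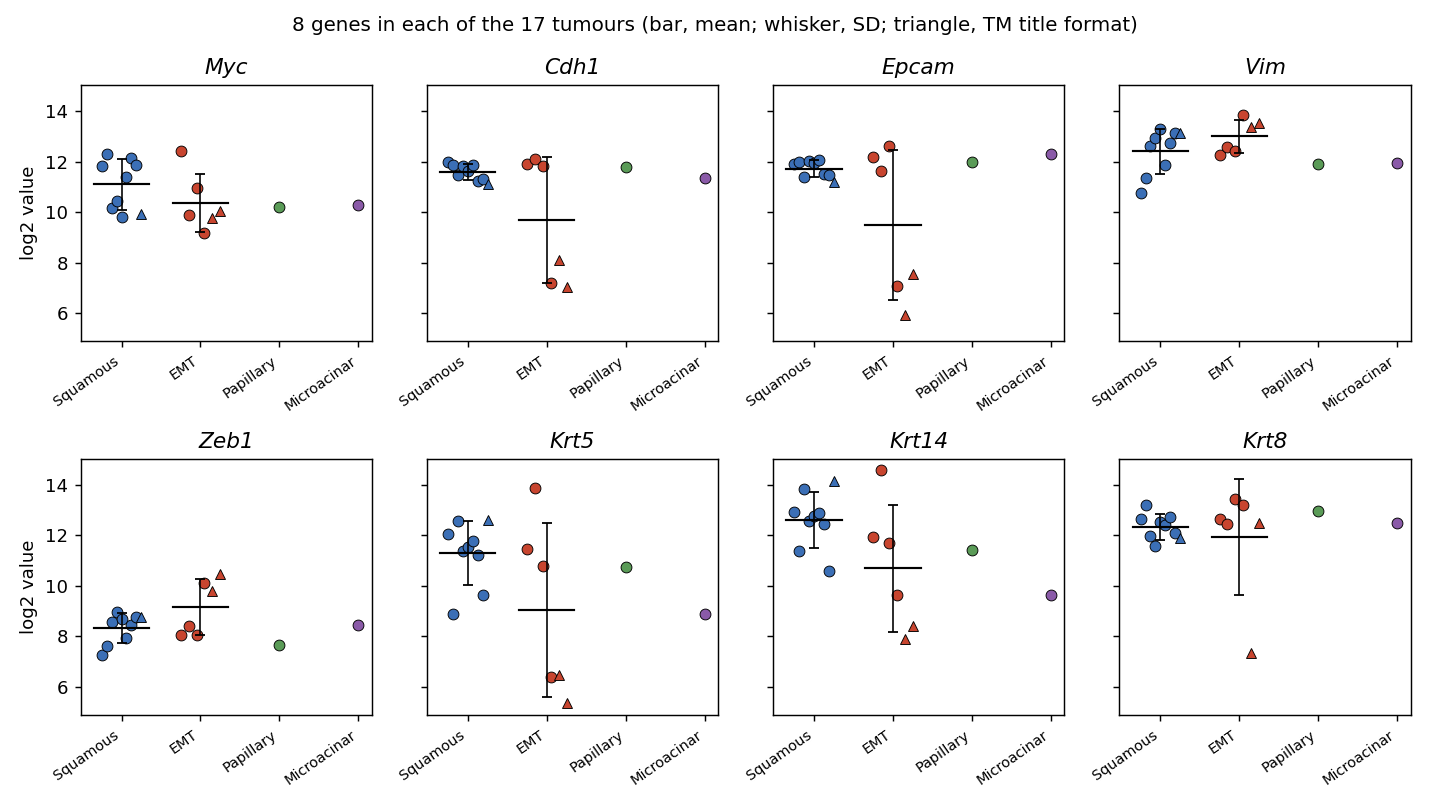
Log2 values of 8 genes (vertical axis) in each tumour, by histology label (horizontal axis); points are tumours, triangles are TM arrays, and bars and whiskers are the mean and SD of Squamous (n = 9) and EMT (n = 6) tumours. Cdh1 in EMT 4, EMT 5 and EMT 6 lay at 7.19, 8.10 and 7.04, below the lowest Squamous value of 11.13.

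Milk and secretory genes lay lower in EMT tumours. The 18 milk genes averaged 8.72 ± 1.73 (SD, n = 6) in EMT against 11.28 ± 1.00 (SD, n = 9) in Squamous tumours, with a median log2 fold change of −2.31, and 4 of 6 EMT tumours lay below the lowest Squamous tumour. Adjusted over the list alone, 15 of the 18 passed, all lower in EMT, and over all genes 0 passed. The largest change was in Muc15, a membrane mucin, at −3.41 (SE 1.03, list-alone adjusted p = 0.0120), followed by Wap, the whey acidic protein, at −3.12 (SE 0.65, list-alone adjusted p = 0.00525) and Btn1a1, a protein of the milk fat globule, at −3.07 (SE 0.77, list-alone adjusted p = 0.00812). The 20 luminal genes had a median log2 fold change of −1.05, with −0.57 without EMT 4 and −0.51 with array weights. Among numbered arrays it was −0.54, the estimate that leaving out Squamous 9 also gives. Adjusted over the list alone 3 passed, all lower: Elf5, a regulator of alveolar differentiation, at −2.95, the claudin Cldn8 at −2.17 and Xbp1, a regulator of secretory capacity, at −0.82. The 14 adipocyte genes had a median log2 fold change of −0.64 with 5 of 6 EMT tumours below the lowest Squamous tumour, and Thrsp, Lpl and Cidea, which act in lipid synthesis and storage, passed adjusted over the list alone at −3.31, −2.60 and −1.72.

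In an exact two-sided permutation test of list means over the 5005 splits of the 15 tumours, added after the data were seen, the adipocyte list (adjusted p = 0.0248) and the milk list (adjusted p = 0.0496) passed the threshold. With histology permuted within each title format, the raw p was 0.00337 for adipocyte and 0.00471 for milk, and neither passed after adjustment over the 31 lists, where the smallest adjusted p was 0.0731. The camera adjusted p was 2.37e-13 for milk, 4.97e-05 for luminal and 3.92e-06 for adipocyte, and for each the adjusted p was 0.499 with an estimated correlation. This value was the smallest adjusted p of that test, and the adjustment gave it to several lists alike.

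Genes of squamous differentiation varied widely within both histologies. The mean of the 32 cornified envelope genes, which build the outer layer of keratinised epithelium, was 8.89 ± 1.39 (SD, n = 9) in Squamous tumours, from 6.33 in Squamous 8 to 11.17 in Squamous 9, and 7.02 ± 1.85 (SD, n = 6) in EMT tumours. EMT 1, EMT 2 and EMT 3 had means of 8.63, 9.19 and 8.14, within the Squamous range, and EMT 4, EMT 5 and EMT 6 had 5.27, 5.94 and 4.96. Rptn, a cornified envelope protein, had the largest fold change of the list at −4.14 (SE 1.46, adjusted p = 0.252). The 22 hair follicle genes had a median log2 fold change of −1.47, with Tchh, the trichohyalin of the inner root sheath, at −3.65 (SE 1.29, adjusted p = 0.252). The camera adjusted p was 1.85e-08 for cornified envelope and 2.15e-06 for hair follicle, and both had an adjusted p of 0.499 with an estimated correlation. Among numbered arrays, the estimate left without Squamous 9 since EMT 5 and EMT 6 then drop out too, the median was −0.83 for cornified envelope, against −1.96 over both title formats, and −0.54 for hair follicle. In both lists 0 members passed over all genes or adjusted over the list alone.

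The keratins of basal cells spread widely among EMT tumours. Krt5 averaged 11.30 ± 1.26 (SD, n = 9) in Squamous and 9.06 ± 3.44 (SD, n = 6) in EMT tumours, and ranged in EMT tumours from 5.35 in EMT 6 to 13.85 in EMT 2. Krt14 ranged in EMT tumours from 7.89 in EMT 5 to 14.57 in EMT 2. The log2 fold changes were −1.75 for Krt5 (SE 1.16) and −1.57 for Krt14 (SE 0.89), with limma adjusted p of 0.506 and 0.433. EMT 2 had the highest mean of the 16 basal keratinocyte genes of all 17 tumours, 11.54, above the highest Squamous tumour at 10.36. The basal keratinocyte list had a median log2 fold change of −0.49, and 0 members passed over all genes or adjusted over the list alone. Its largest change was in Krt17 at −1.90 (SE 1.21, adjusted p = 0.486). The camera adjusted p of the list was 0.186, and 0.830 with an estimated correlation. The calls that follow used the preset correlation. The list was called lower without EMT 2 (median −0.87, camera adjusted p = 0.000577), without the title format term (−0.86, adjusted p = 0.0252) and with array weights (−0.45, adjusted p = 0.0270), and its median turned to 0.05 among numbered arrays, the one estimate that leaving out Squamous 9 also gives. Krt8, a keratin of simple epithelia, was 13.20 in EMT 4, 7.35 in EMT 5 and 12.50 in EMT 6, against 12.33 ± 0.50 (SD, n = 9) in Squamous tumours. Its log2 fold change was 0.05 (SE 0.65, adjusted p = 0.984), and −0.40 without the title format term.

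Cell cycle genes lay higher on average in EMT tumours. The proliferation mean was 9.33 in EMT 1, 9.27 in EMT 3 and 9.48 in EMT 6. It was 8.98 in EMT 2, 8.87 in EMT 4 and 8.82 in EMT 5, within the Squamous range. The 29 proliferation genes averaged 9.13 ± 0.27 (SD, n = 6) in EMT and 8.64 ± 0.35 (SD, n = 9) in Squamous tumours, with a median log2 fold change of 0.45 and 3 of 6 EMT tumours above the highest Squamous tumour at 8.99, and 9 passed adjusted over the list alone, all higher. Cdk1, the kinase of mitotic entry, was higher by 0.95 (SE 0.19, list-alone adjusted p = 0.00670), with 6 of 6 EMT tumours above the highest Squamous tumour. Aurka, a mitotic kinase, was higher by 0.77 (SE 0.17, list-alone adjusted p = 0.00706), also in 6 of 6 EMT tumours. The 15 genes of Ras-MAPK output had a median log2 fold change of 0.56, and 4 passed adjusted over the list alone, all higher: the transcription factor subunit Fosl1 at 1.61, the ERK phosphatase Dusp6 at 1.23 and the pathway inhibitors Spred2 and Spred1 at 0.56 and 0.46. The 19 genes of hypoxia and glycolysis had a median log2 fold change of 0.40, and P4ha1, a prolyl hydroxylase of collagen, passed adjusted over the list alone at 1.27 (SE 0.30). EMT 4 had the lowest hypoxia and glycolysis mean of the 17 tumours, 9.16, the other way from the list. Without it the median was 0.63, and without EMT 2 it was 0.26 and the call ended (camera adjusted p = 0.0663). Over all genes 0 members of these 3 lists passed. The camera adjusted p was 1.35e-10 for proliferation, 8.10e-05 for Ras-MAPK output and 0.000317 for hypoxia and glycolysis, and with an estimated correlation the adjusted p was 0.499, 0.499 and 0.577. By exact permutation of list means the adjusted p was 0.0929, 0.0929 and 0.181.

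B and plasma cell genes had a median log2 fold change of −0.55. Jchain, the joining chain of secreted antibodies, was at −3.46 and the B cell marker Ms4a1 at −1.29. Both passed adjusted over the list alone, but not over all genes (limma adjusted p = 0.190 and 0.213). The Ms4a1 mean in EMT tumours was 4.37, below the lower quartile of every array, the lowest of which was 5.24. Neutrophil genes had a median of −0.86 with S100a9, a calcium-binding protein of neutrophils, at −2.29 (SE 0.86, adjusted p = 0.268), class II antigen presentation genes −0.61 with H2-Ab1 at −1.13 (SE 0.51, adjusted p = 0.337), and T and NK cell genes −0.15. The 25 fibroblast matrix genes had a median of 0.54 with the matrix protein Fbln2 at 1.05 (SE 0.53, adjusted p = 0.376), and the 18 skeletal muscle genes 0.78 with the myosin Myh1 at 2.02 (SE 1.67, adjusted p = 0.597). Camera called these lists, and with an estimated correlation the adjusted p was 0.499 for B and plasma cell, neutrophil and class II, 0.815 for T and NK cell, and 0.830 for fibroblast matrix and skeletal muscle. The fibroblast matrix median was −0.10 with array weights (camera adjusted p = 0.147), 0.05 without EMT 4 (camera adjusted p = 0.963) and 0.28 without Squamous 1 (camera adjusted p = 0.310), and the skeletal muscle median was −0.04 without EMT 4, whose muscle gene mean was 10.83. The call ended in 9 of 13 alternative fits for skeletal muscle and in 5 of 13 for fibroblast matrix, quantile normalization among both (camera adjusted p = 0.118 and 0.202). The neutrophil median was −0.52 among numbered arrays, the estimate that leaving out Squamous 9 also gives, and the T and NK cell median was −0.04 without Squamous 8 (camera adjusted p = 0.0629). Macrophage genes had a median of 0.12 and were not called (camera adjusted p = 0.917), but were called lower with array weights (median −0.23, adjusted p = 0.0243), with means of 11.90 in EMT 5 and 11.58 in EMT 6, above the highest Squamous tumour at 10.63; Cd14, a receptor of myeloid cells, was at −1.20 (SE 0.31) and passed adjusted over the list alone.

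Of the other lists, oxidative phosphorylation had a median log2 fold change of −0.17 (camera adjusted p = 0.00272, and 0.556 with an estimated correlation). The call ended without EMT 2 (median −0.07, camera adjusted p = 0.0658) and with array weights (median −0.05, camera adjusted p = 0.151). Wnt targets had a median of −0.41 (camera adjusted p = 0.0517, and 0.758 with an estimated correlation). At the preset correlation they were called lower in 7 of 13 alternative fits and without any 1 of 5 tumours. EMT 1 was among these tumours (median without it −0.88, camera adjusted p = 2.14e-05). The largest change among Wnt targets was in Wif1, a secreted Wnt inhibitor, at −3.52 (SE 1.30, adjusted p = 0.263). Myc targets had a median of −0.05 and a mean of 0.01 (camera adjusted p = 0.909), and were called higher with array weights (median 0.0667, adjusted p = 0.0282). Their member Cdk4, a kinase of the G1 phase, was higher in EMT by 0.60 (SE 0.09, list-alone adjusted p = 0.000608). Endothelial genes had a median of 0.07 and a mean of −0.00142 (camera adjusted p = 0.919), and were called lower with array weights (median −0.24, adjusted p = 0.000458). Their member Vwf, the von Willebrand factor, was at −0.97 and passed adjusted over the list alone. Camera did not call the smooth muscle and myoepithelial, pericyte, mast cell, TGF-beta response, Notch targets, interferon, immediate early and heat shock, ribosomal protein and housekeeping lists, whose medians were −0.16, 0.05, 0.03, 0.06, −0.07, −0.13, 0.13, −0.04 and −0.07. Among these, interferon genes were called lower among numbered arrays (median −0.53, camera adjusted p = 2.09e-05) and with array weights (median −0.33, camera adjusted p = 0.0159). They were also called lower without EMT 5 (median −0.37, camera adjusted p = 0.00210), whose interferon mean was 9.87. These calls used the preset correlation. In the main fit the camera adjusted p of the interferon list was 0.943 with an estimated correlation. Among numbered arrays the exact permutation p of its mean was 0.137. Within TM arrays its median was 1.47, the other way and without a call. Notch targets were called lower without EMT 2 (median −0.24, camera adjusted p = 0.0317). Adjusted over the list alone, the smooth muscle genes Smtn at 0.96 and Lmod1 at −0.43 and the pericyte gene Higd1b at 0.61 passed.

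Over all 12393 genes, 0 changed between EMT and Squamous tumours at an adjusted p under 0.05 with limma, and the smallest adjusted p was 0.0982. At an unadjusted p under 0.05 there were 1778 genes, 1001 higher and 777 lower in EMT. Camera called 17 of the 31 lists, camera with an estimated correlation 0, and fry, which tests whether a list's genes move on balance one way, 0 (smallest adjusted p = 0.0803), while fry's test for change in either direction called 1, milk (adjusted p = 0.0284). Without EMT 1, 14 genes passed, 8 higher and 6 lower in EMT. The 3′ minus 5′ value of the beta-actin control probe sets is higher where RNA is less intact. It was 0.59 ± 0.13 (SD, n = 6) in EMT and 0.78 ± 0.11 (SD, n = 9) in Squamous tumours (exact permutation, two-sided, p = 0.0126). By this value RNA was less intact in the Squamous tumours. The exact permutation p was 0.0808 among numbered arrays and 0.00440 after quantile normalization. For Gapdh the value was 0.10 ± 0.16 in EMT and 0.19 ± 0.11 in Squamous tumours (exact permutation p = 0.247).

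**Figure D2:**
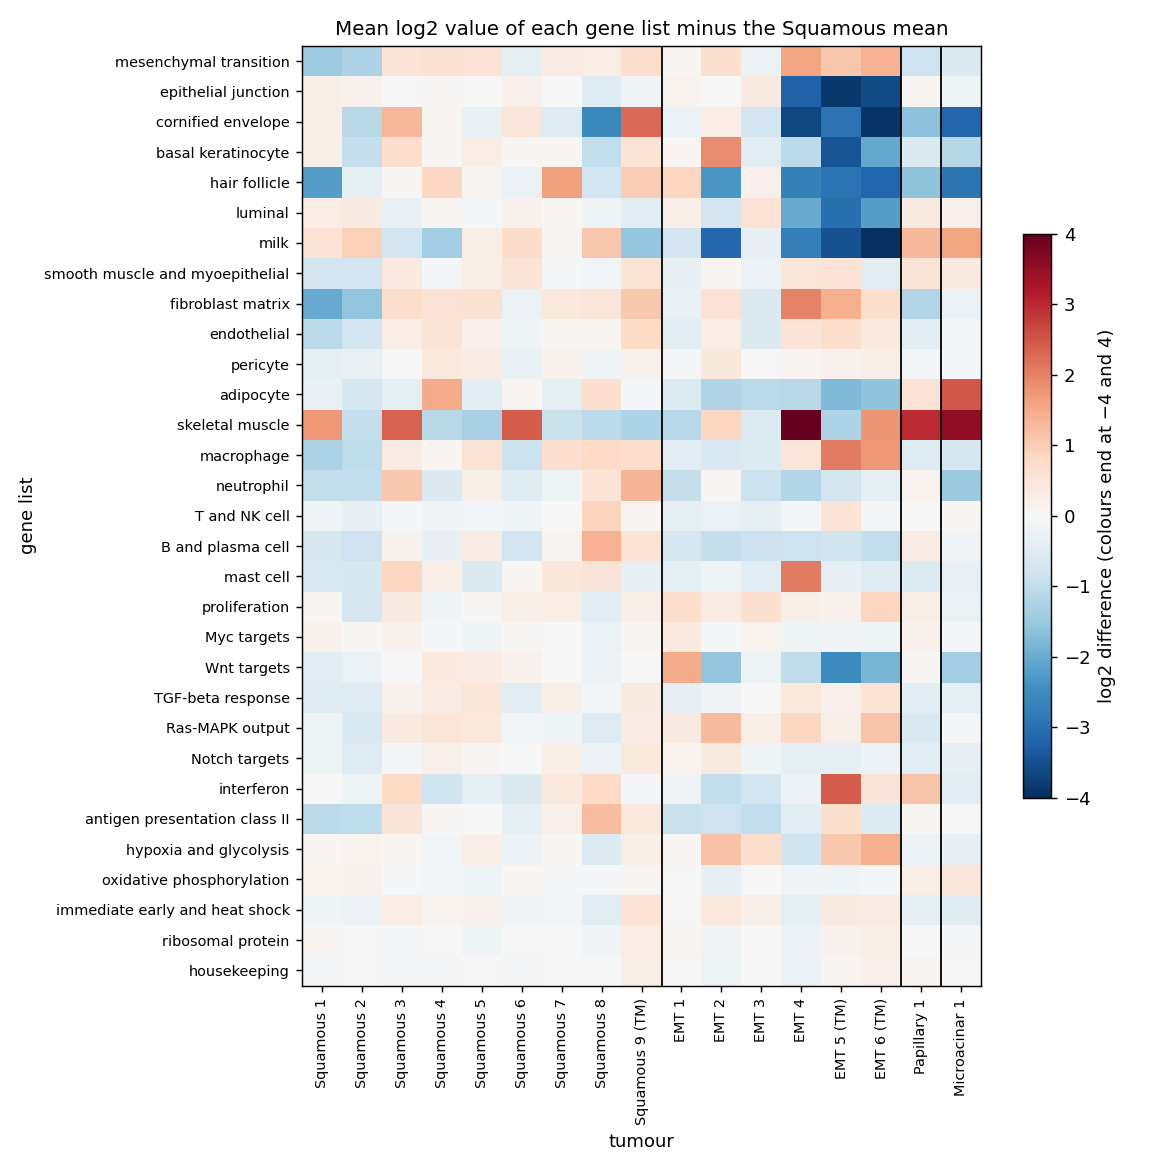
Mean log2 value of each of the 31 gene lists (rows) in each of the 17 tumours (columns) minus the mean of the 9 Squamous tumours, as colour, red higher and blue lower; black lines divide the histology labels. The epithelial junction row lies at −3.23, −3.85 and −3.57 in EMT 4, EMT 5 and EMT 6 and at 0.13, 0.03 and 0.35 in EMT 1, EMT 2 and EMT 3.

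The principal components show the main directions of variation without a choice of genes. PC1 held 40.7% of the variance, with scores of 56.2 for EMT 4, 96.9 for EMT 5 and 89.3 for EMT 6. EMT 1 and EMT 3 scored −24.6 and −25.5, between the lowest and highest Squamous scores of −44.5 and 18.0, and EMT 2 scored 19.3, above them. EMT 5 and EMT 6, both TM arrays, had the highest scores of all tumours. Squamous 9, also a TM array, had the highest Squamous score. PC1 thus went with title format as well, and its share of the variance is not that of histology alone. With title format means removed, PC1 held 31.2% of the variance. The mean PC1 score was 35.3 ± 54.2 (SD, n = 6) in EMT and −16.7 ± 20.3 (SD, n = 9) in Squamous tumours (exact permutation, two-sided, p = 0.0176; p = 0.0128 with title format means removed and p = 0.0957 with genes scaled to unit variance). PC2 held 15.4% and PC3 10.1% of the variance, with exact permutation p of 0.353 and 0.197. The highest PC3 score was that of EMT 2 at 55.8. These 3 p-values were not adjusted for one another.

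**Figure D3:**
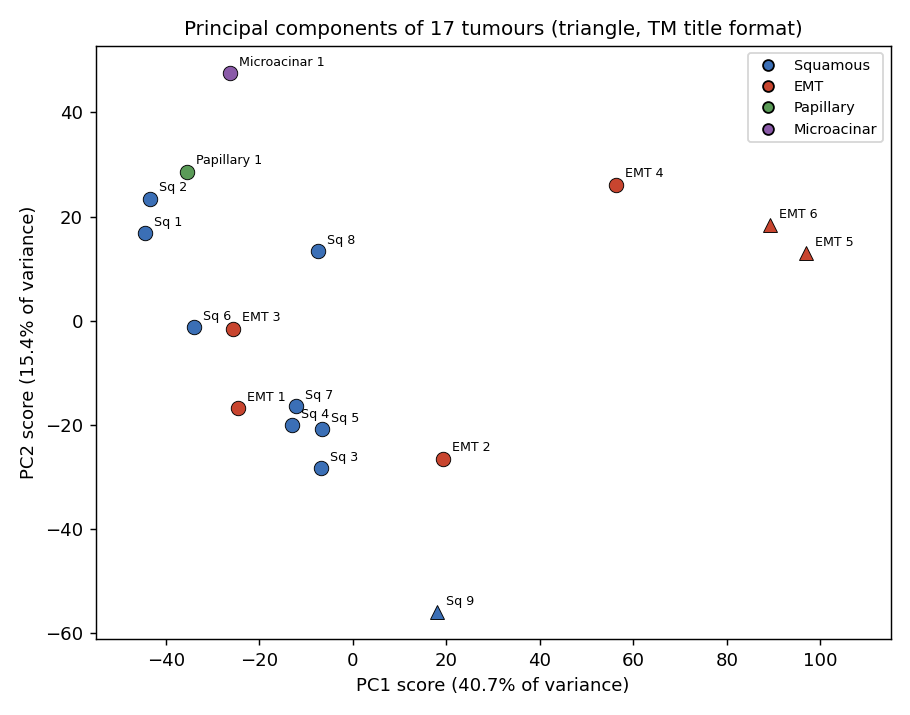
PC1 score against PC2 score of the 17 tumours, computed from 12393 centred genes, with the share of variance on each axis; colours are histology labels and triangles TM arrays. EMT 4, EMT 5 and EMT 6 lie at PC1 scores of 56.2, 96.9 and 89.3, and Squamous 9 at 18.0.

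The Papillary and Microacinar tumours were each compared with the Squamous and the EMT means, without a test, since each is 1 tumour. The Microacinar tumour had the highest milk gene mean of the 17, 12.87, and an adipocyte gene mean of 10.14 against 7.67 ± 0.68 (SD, n = 9) in Squamous tumours. Its cornified envelope mean of 5.71 lay below the lowest Squamous tumour at 6.33. The genes furthest above all other tumours were Cidea, a lipid droplet protein, at 12.12, which was 2.12 above the next tumour, then Gpd1, Lao1, Gstt1, Acad11 and Chpt1 with gaps of 1.85, 1.33, 1.04, 1.01 and 0.99. Bmp2, a secreted growth factor, at 4.41 lay furthest below, with a gap of −2.38, followed by Apcdd1, Lgals3 and Scd2 with gaps of −1.44, −1.06 and −1.02. Against the Squamous mean 20 of the 31 lists lay outside the central 95% of random lists, 5 above and 15 below, and against the EMT mean 21.

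The Papillary tumour had a milk gene mean of 12.58 and an interferon mean of 8.59 against 7.44 ± 0.57 (SD, n = 9) in Squamous tumours. The genes furthest above all other tumours were the interferon-induced Oas2 with a gap of 0.87 and Apobec3 with 0.54, then Slc39a8, Fkbp11, Gabrp and Abcg2 with 0.52, 0.49, 0.47 and 0.40. Nkain1, Ttc39b, Pfkp and Bok lay furthest below, with gaps of −0.66, −0.43, −0.41 and −0.37. Its fibroblast matrix mean was 9.06, against 10.22 ± 1.08 (SD, n = 9) in Squamous tumours. Its skeletal muscle mean was 9.46 and that of the Microacinar tumour 10.02, against 6.48 ± 1.64 (SD, n = 9) in Squamous tumours. Against the Squamous mean 24 of the 31 lists lay outside the central 95% of random lists, 10 above and 14 below, and against the EMT mean also 24. Genes of a list vary together within a tumour, so these shares describe the tumour and do not test it.

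The relation of Myc to the mean of its targets list was taken within each histology. In the 9 Squamous tumours Pearson's r was −0.0238 (exact permutation p = 0.950) and Spearman's rho −0.0833 (exact permutation p = 0.843), and r was −0.198 without the 2 tumours farthest from the median of Myc. In the 6 EMT tumours r was 0.958 (exact permutation p = 0.0181, adjusted p = 0.0361 over the 2 histologies) and rho 0.657 (exact permutation p = 0.175, adjusted p = 0.350). Without the 2 farthest tumours, EMT 1 and EMT 3 with Myc values of 12.40 and 10.95, r was 0.155. The 4 tumours left had Myc values of only 9.18 to 10.04. A narrowed range alone could lower r, so this step cannot tell whether the relation rests on those 2 tumours. The numbered arrays hold 4 EMT tumours, under the 6 set before the data were examined as the least for a correlation within one title format.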

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

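All tests of explanations in this part were chosen after the results were seen. Of 142 sets of values within a histology, 10 held a tumour far from the others by Dixon's criterion, and chance marks about 1 in 20.

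In EMT 5 the T and NK cell mean was 6.29, against 5.38 to 5.70 in the other EMT tumours, the class II antigen presentation mean was 9.15 against 7.50 to 8.06, H2-Ab1 was 11.24 against 9.03 to 9.75, and Krt8 was 7.35 against 12.46 to 13.45. In EMT 4 the mast cell mean was 8.09 against 5.53 to 5.82 in the others. In EMT 6 Cdk1 was 10.88 against 9.85 to 10.20. In Squamous 8 the epithelial junction mean was 9.14 against 9.51 to 9.88 in the other Squamous tumours, the T and NK cell mean was 6.64 against 5.41 to 5.82, and Rptn was 4.21 against 8.86 to 13.37. In Squamous 9, a TM array, the housekeeping mean was 11.82 against 11.47 to 11.57.

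The low epithelial junction genes of EMT 4, EMT 5 and EMT 6 were weighed against technical explanations. EMT 5 and EMT 6 are TM arrays, but EMT 4 is a numbered array and lay below the lowest numbered Squamous tumour, a difference of −2.73 in the list mean, which argues against the array set as the whole source. A swap of labels with a Squamous tumour stays open: 0 Squamous tumours lay closer to the lowest EMT tumour than to the Squamous median, but EMT 1, EMT 2 and EMT 3 lie at the Squamous level too, so a swapped partner need not stand out. Fewer epithelial cells would lower Krt8 and Krt18 too, yet the lower of the means of these keratins in EMT 4 and EMT 6 differed from the Squamous mean by only −0.17. In EMT 5 the difference was −5.20, and fewer epithelial cells and loss of keratins by the tumour cells cannot be told apart there, since both would lower the keratins, and macrophage genes lay at 2.52 and B and plasma cell genes at −1.10 Squamous SDs from the Squamous mean.

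Chance was examined by 100 splits of the 15 tumours into groups of 6 and 9, the real one included. For genes past the threshold all 100 splits gave as many as the real 0, which any split must, so that comparison says nothing about chance; 2 of the 99 other splits gave any gene, 10 and 4. For genes at an unadjusted p under 0.05, 5 of the 100 splits gave at least the real 1778, with 2770 the highest other, so chance is not excluded. For lists called by camera, 24 of the 100 splits gave at least the real 17, so chance is not excluded there either. The other splits gave 6 to 24 lists, so camera at the preset correlation called lists in every split.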

How the results depend on the processing

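The exact permutation tests of list means and the setting without genes equal on the TM arrays were added after the data were seen. The count of 0 changed genes held under every alternative except one, the TM arrays alone set aside: leaving out one tumour each gave 0 to 14, with the 14 reached without EMT replicate 1, and without genes equal on the TM arrays it was 0 (1691 at an unadjusted p under 0.05). Camera called 15 to 18 lists under every such alternative fit and 15 to 18 when one tumour was left out. The count was 0 with an estimated correlation, 0 with fry, 2 with the exact permutation test and 0 with that test within title formats. Leaving out 1 tumour ended the camera call of skeletal muscle for 8 of the 15 tumours, of fibroblast matrix for 6, of T and NK cell for 5, and of hypoxia and glycolysis and of oxidative phosphorylation for 1 each, and it gave Wnt targets a call for 5, interferon for 2, and basal keratinocyte, Notch targets and ribosomal protein for 1 each. Without Squamous replicate 9, EMT replicates 5 and 6 drop out through the title format term, so that estimate is the numbered one and no separate evidence. Within TM arrays 1 Squamous tumour stands against 2 EMT tumours, so their medians are values without a call. Of the 13 other alternative fits, the call ended in 9 for skeletal muscle, 5 for fibroblast matrix, 3 of 12 for T and NK cell, and 1 each for mesenchymal transition and oxidative phosphorylation, and a call appeared in 7 for Wnt targets, 2 each for basal keratinocyte and interferon, and 1 each for endothelial, macrophage, Myc targets and ribosomal protein. List medians turned sign: fibroblast matrix was −0.17 within TM arrays and −0.10 with array weights, endothelial −0.24 in both, macrophage −0.23 and Myc targets 0.0667 with array weights, and skeletal muscle −0.0410 without EMT replicate 4, in a range up to 1.28 without EMT replicate 1. Other list values, those of the TM arrays counted in, kept their direction and side of the threshold in 804 cases, were weaker in 76, stronger in 27 and turned sign without a call in 45, basal keratinocyte (0.0536 among numbered arrays) among them, and those of named genes did so in 1073 cases, were stronger in 1 and moved in 14. The beta-actin difference was −0.143 among numbered arrays (exact permutation p = 0.0808) and −0.220 after quantile normalization (exact permutation p = 0.00440). PC1 differed by 0.944 pooled SDs with scaled genes (exact permutation p = 0.0957). Myc and its targets in Squamous tumours had r = 0.0987 on numbered arrays and 0.199 after quantile normalization. The list counts of the single tumours and the Gapdh difference kept their side. Fewer tumours remain within each title format and in the settings without a tumour; for the other settings the cause was not tested. The fit of all 17 tumours in 4 groups equals the one reported by construction. The trended and robust fit leaves the list tests unchanged by construction. Neither is separate evidence among the 13 alternative fits of the lists. A random block for the title number could not be fitted, Myc within the 4 numbered EMT tumours was left out as under the planned 6, and offsets for linear values did not apply. The number of tumours and the signal over background of the arrays limit what small changes can be seen.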

Other observations

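Skeletal muscle genes were present at high levels in tumours of all 4 labels. Their mean was 10.83 in EMT 4, 10.02 in the Microacinar tumour, 9.46 in the Papillary tumour, 8.91 in Squamous 6, 8.83 in Squamous 3 and 8.26 in EMT 6, and 5.20 in the lowest tumour, Squamous 5. Interferon genes were highest in EMT 5 at 9.87, with the Papillary tumour next at 8.59. B and plasma cell genes were highest in Squamous 8 at 7.72, where Jchain reached 13.47. Tpsab1, a mast cell tryptase, was 11.43 in EMT 4 and at most 8.38 elsewhere. Wnt target genes were highest in EMT 1 at 9.46, where Wif1 was 12.49, and lowest in EMT 5 at 5.42.

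All tests of hypotheses in this part were chosen after the results were seen. The first hypothesis was that the EMT label covers a wider range of expression profiles than the Squamous label. The mean pairwise distance was 0.985 among EMT and 0.641 among Squamous tumours (exact permutation, two-sided, p = 0.0456), and among numbered arrays it was 0.861 and 0.591 (exact permutation p = 0.0970). EMT tumours have more TM arrays, 2 of 6 against 1 of 9, so the hypothesis stays open. The second was that the 3 TM arrays were summarised apart from the other 14. They share one exact value in 2989 probe sets, 1409 of the genes tested, and any 3 numbered arrays share at most 1, which is consistent with it. The third was that Squamous 7 and Squamous 8, which share a title number, have alike profiles. Their deviations from the numbered Squamous mean correlated across genes, which are not independent replicates, at r = 0.228, rank 6 of 28 pairs, with a highest of 0.440 and a median of −0.200, which leaves it undecided.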
